A study of Homo sapiens with 15 samples.

How the data were processed

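The study measured messenger RNA 3' ends by MACE-seq, which reads the ends of polyadenylated transcripts and removes amplification copies by unique molecular identifiers, in 15 libraries of total RNA from HEK293T cells. The groups are mock, day 0, day 3, day 12 and day 28, with 3 libraries each. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq, aligned to GRCh38 with Bowtie2 and assigned to genes with HTSeq. Their versions and the annotation release are not given in the sources used here. The deposited table holds the count of reads per gene and library as the authors gave it, and every count is a whole number. Its columns name day 2 where the sample titles name day 3; the label gives 48 h of induction, and the columns were matched to the titles on that ground, with 0 columns left unmatched. Gene types and coordinates come from GENCODE release 29 on GRCh38, which may differ from the release the submitters used.

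Depth ran from 3368528 counts (day 0 replicate 3) to 10051638 (mock replicate 1). Given this depth, the scatter between replicates in excess of counting noise was small outside day 28: chi-square per degree of freedom between replicates was 1.32 to 3.32 in the other groups and 10.5 to 28.4 on day 28. A low count carries a wide error, so ratios against 1 to 3 counts are given with a 95% interval that covers counting error only, and ratios against 0 counts as a lower bound with a floor of 3 counts over the group.

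Differences were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 14741, and libraries scaled by trimmed means (TMM). A quasi-likelihood model was fitted to all 15 libraries; the common biological coefficient of variation was 0.102. A gene is called changed when its adjusted p, by the method of Benjamini and Hochberg over all genes tested, is under 0.05. Standard errors were derived from the log2 change and its F statistic. Levels are CPM scaled by the same factors; CPM of all counts are named where used. Because tags of 3' ends can match several genes, the share of 31-base words in the last 300 bases that other transcripts also hold was computed for each gene. Coding genes with under 10% shared words, 9794 of the tested genes, are called coding genes with unique ends. Processed pseudogenes number 1461 of the tested genes.

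The comparisons were day 0 with mock, day 3, day 12 and day 28 each with day 0, day 3 with mock, day 12 with day 3 and day 28 with day 12, plus a joint test of the fusion groups over time and a count of genes changed on day 3 and in the same direction on day 28. These, with the filter, scaling, thresholds and main alternatives, were fixed before the data were examined. Comparisons of day 28 with day 3 and of day 12 and day 28 with mock were added later. In simulations without change, built on the fitted model, 10 draws gave the overlap and correlation that the shared day 0 libraries alone produce, and those that shared day 3 libraries produce.

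A file of 48 gene lists written from general knowledge of pathways before any test was used for groups of genes; lists with fewer than 5 tested members were left out. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes and adjusted over lists. A list is called changed on that test, and the adjusted p with an estimated correlation is given beside it. The counts of members that rose or fell use the adjustment over all genes, and those over the list alone adjust within the list.

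Genes named in the text were selected by rule: the 6 with the largest change in each direction among called genes with a gene symbol, at least 5 CPM in the higher group and libraries that do not overlap between groups, 2 members of each of the 6 lists with the smallest p, and genes fixed beforehand, KMT2A, AFF1, HOXA9, HOXA10, MEIS1, MYC, CDKN1A, ATF4 and EGR1. The rule was repeated within coding genes with unique ends after the data had been seen, because pseudogenes filled the first selection. Any other list member given as an example was chosen after its values were seen.

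Alternatives included DESeq2 1.42.0 and limma voom, a filter of 5 CPM in 3 libraries, scaling by library totals alone, fits within coding genes with unique ends, a test against a fold of 1.5, fits of only the groups compared, rotation tests (fry) of lists, a term for the replicate number, and leaving out each library in turn. Principal components were taken from the 1000 most variable genes on log2 CPM with a prior count of 2. Changed genes were also counted for other divisions of the same libraries, 10 for each comparison of 3 with 3 and 100 draws for the joint test and the overlap. With 3 libraries in each group, the smallest p of a permutation of a single gene would be 0.1, so tests rest on the model. The procedure was tested on simulated data: with 200 of 14741 genes changed it found 37.3% of those changed 1.5-fold, 61.2% of those changed 2-fold and 93.9% of those changed 4-fold, with 131 calls of which 2.29% were false. No reads or other raw files were used, and no library was left out of the main results.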

Results

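RNA 3' ends were counted in 15 libraries of HEK293T cells, a human embryonic kidney line that takes up foreign DNA easily. The t(4;11) translocation of acute leukaemia joins KMT2A (MLL), the gene of a histone H3 lysine 4 methyltransferase, to AFF1 (AF4), the gene of a scaffold of the transcription elongation machinery. The series asks how transcription changes over time in cells that hold the resulting fusion proteins. Per the labels, the mock cells carry an empty vector, the cells of day 0, day 12 and day 28 express MLL-AF4 constitutively, and those of day 3 in addition express AF4-MLL, induced for 48 h with 1 µg/ml doxycycline. The labels of day 12 and day 28 do not say whether AF4-MLL had been induced earlier. Each group holds 3 libraries, and the labels do not say that these came from separate cultures. All p-values therefore measure only the spread between these samples, which may be technical. Levels are in CPM, counts scaled to library size, given as mean ± SD with n = 3 per group.

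The libraries of mock, day 0, day 3 and day 12 each lay close together, while those of day 28 were spread out. Over the protein-coding genes whose 3' ends are not shared with other transcripts, component 1 held 42.2% and component 2 held 21.2% of the variance. Component 1 set day 3 apart from day 12, and component 2 set mock apart from the fusion lines. Over all genes, component 1 held 66.5% and placed day 3 and day 28 on the side away from mock, day 0 and day 12. Of 176 genes more than 4-fold higher on both of these days than in the other groups, 154 are processed pseudogenes, copies of messenger RNAs scattered through the genome, hence the name pseudogene divide for this separation. As a whole, processed pseudogenes drew 19.4 ± 0.186% of counts on day 3, 14.1 ± 0.449% in mock, 15.2 ± 0.266% on day 0 and 13.5 ± 0.342% on day 12 (n = 3 each). On day 28 their share was 18.9% in replicate 1, but 15.7% and 15.9% in replicates 2 and 3, near day 0. Mitochondrial transcripts made up 2.51 ± 0.477% of counts in mock, 9.0 ± 0.471% on day 0, 7.64 ± 0.504% on day 3, 8.48 ± 0.0137% on day 12 and 7.87 ± 1.45% on day 28 (n = 3 each).

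**Figure D1:**
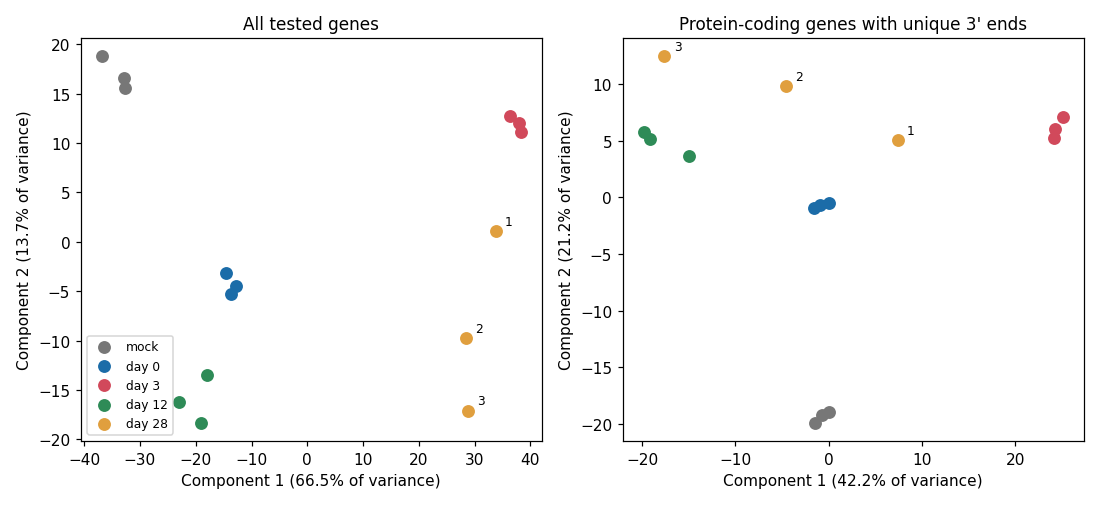
Principal components of log2 CPM, 1 point per library, coloured by group and with the replicate numbers of day 28 written beside the points. Left, all tested genes, where component 1 (66.5% of variance) places day 3 and day 28 together. Right, protein-coding genes with unique 3' ends, where component 1 (42.2%) runs from day 12 to day 3.

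KMT2A and AFF1 were examined first, as a check of the labels. KMT2A (GRCh38 chromosome 11, 118436464 to 118526832) stood at 313 ± 25.1 CPM on day 3 against 33.0 ± 4.45 on day 0 (n = 3), a log2 fold change of 3.23 (SE 0.15, edgeR adjusted p = 4.28e-13). AFF1 (chromosome 4, 86935002 to 87141054) rose from 12.7 ± 0.989 to 22 ± 2.97 CPM (0.78, SE 0.16, adjusted p = 7.65e-04). AF4-MLL ends in KMT2A sequence and MLL-AF4 ends in AFF1 sequence, so 3' tags of a construct could reach these genes. AFF1 did not rise from mock to day 0 (11.9 ± 1.75 to 12.7 ± 0.989 CPM, log2 0.10, adjusted p = 0.704), and KMT2A fell there (56.7 ± 8.51 to 33.0 ± 4.45 CPM, −0.76, SE 0.15, adjusted p = 0.00135). On day 12 and day 28, KMT2A was back at 29.4 ± 4.24 and 41.9 ± 9.48 CPM, with log2 changes from day 0 of −0.19 (adjusted p = 0.469) and 0.33 (adjusted p = 0.181). The counts speak for the day 3 label, but transgene tags may lie outside the counted part of either gene, so the counts of AFF1 say little about MLL-AF4.

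**Figure D2:**
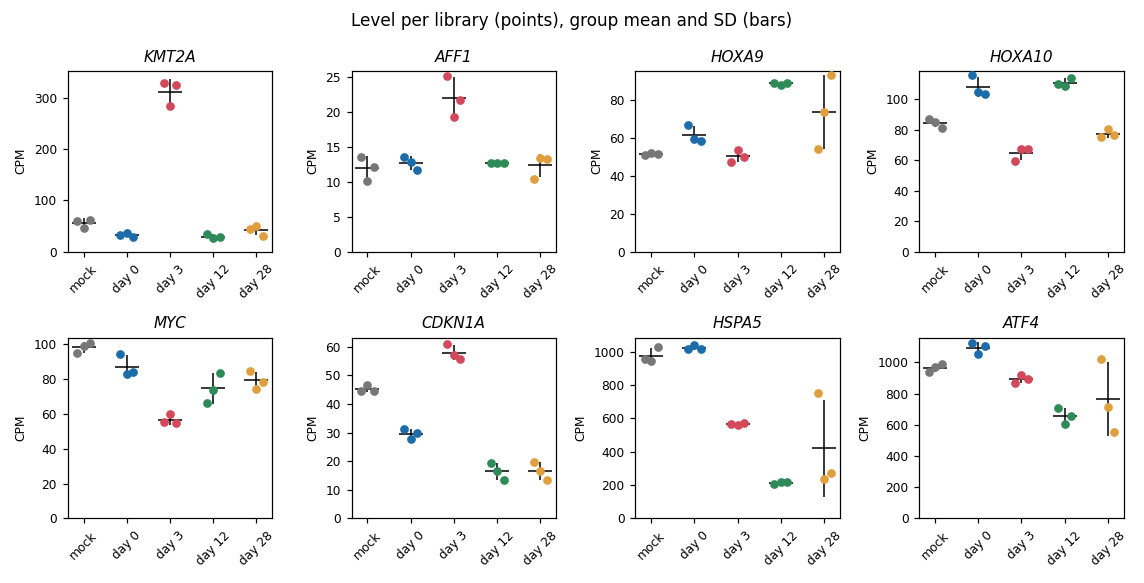
CPM of 8 genes by group, 1 point per library, with bars for the group mean ± SD (n = 3). KMT2A rises on day 3 (313 CPM), CDKN1A rises on day 3 (57.9 CPM) and falls on day 12 (16.4 CPM), and HSPA5 is low on day 12 (214 CPM) and spread out on day 28.

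Cells with MLL-AF4 on day 0 differed from mock in mitochondrial, hypoxia, glycolysis, heat shock and chromatin remodeller genes, among others. MT-CO1 (mitochondrial genome, 5904 to 7445), which encodes subunit 1 of cytochrome c oxidase, rose from 343 ± 68.6 to 13090 ± 478 CPM, and MT-CYB, which encodes cytochrome b, from 1793 ± 311 to 8570 ± 147 CPM (n = 3). BNIP3, a hypoxia-induced gene of mitophagy, rose from 112 ± 10.2 to 362 ± 18.3 CPM and LDHA, the lactate dehydrogenase of glycolysis, from 683 ± 19.6 to 1482 ± 188 CPM. The inducible chaperone gene HSPA6 (chromosome 1, 161524540 to 161526910) fell from 45.3 ± 1.54 to 0.17 CPM. HBD (chromosome 11, 5232678 to 5243657), the delta-globin gene, was at 0 in mock and at 170 ± 5.63 CPM on day 0.

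In edgeR these were log2 changes of 5.25 for MT-CO1 (SE 0.15, adjusted p = 8.53e-17), 2.26 for MT-CYB (SE 0.13, adjusted p = 7.45e-11), 1.69 for BNIP3 (SE 0.22, adjusted p = 1.29e-05) and 1.12 for LDHA (SE 0.12, adjusted p = 8.57e-07). MT-CO1 shares 80.4% of its 3' end sequence with nuclear copies, so part of its reads may be counted elsewhere. HSPA6 was 253 times higher in mock (counting interval 86.2 to 1230, from 3 counts on day 0). HBD was at least 1250-fold higher on day 0, against a floor of 3 counts over the group. FHOD3, a formin that assembles actin in heart muscle, rose from 11.4 ± 0.346 to 1187 ± 85.1 CPM (6.70, SE 0.32, adjusted p = 1.13e-12), although the end of FHOD3 overlaps another gene. In each gene that is given as changed in this report, all 3 libraries of a group lay above all 3 of the other unless stated, an arrangement that 10% of genes without a difference would show.

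Of the 15 genes of the mitochondrial-encoded list, which holds messenger and ribosomal RNAs, 14 rose and 0 fell (median log2 1.76; adjusted over the list alone, 14 rose). Their camera adjusted p = 2.26e-23, and adjusted p = 0.131 with an estimated correlation. The list leaves out transfer RNAs, of which MT-TV fell from 29.9 ± 4.97 to 2.47 ± 1.78 CPM (log2 −3.79, SE 0.28, adjusted p = 2.80e-09) and MT-TD rose from 0.135 ± 0.140 to 11.4 ± 1.67 CPM (5.96, SE 0.43, adjusted p = 2.50e-09, n = 3). Among 20 hypoxia genes, 14 rose and 6 did not pass (median 0.75, 14 over the list alone, camera adjusted p = 5.58e-08, adjusted p = 0.405 with an estimated correlation). ADM, the gene of the vasodilator adrenomedullin, gained 1.22 (adjusted p = 5.89e-05). Glycolysis genes rose in 12 of 21 cases with 0 falling (13 over the list alone, camera adjusted p = 7.01e-08, adjusted p = 0.271 with an estimated correlation). PGK1 was among them (358 ± 14.4 to 649 ± 36.1 CPM, n = 3). Heat shock genes fell in 8 of 20 cases and 0 rose (median −0.42, 9 over the list alone, camera adjusted p = 1.27e-06, adjusted p = 0.431 with an estimated correlation). HSPB1, the small heat shock protein 27 gene, went from 181 ± 5.30 to 99.4 ± 2.63 CPM (n = 3), but shares 38.4% of its 3' end sequence with other transcripts. Of 27 chromatin remodeller genes, 11 fell and 16 did not pass (median −0.33, 17 fell over the list alone, camera adjusted p = 2.08e-06, adjusted p = 0.271 with an estimated correlation). PBRM1, a SWI/SNF subunit gene, fell from 45.5 ± 1.34 to 27.0 ± 1.38 CPM (log2 −0.74, adjusted p = 1.50e-05, n = 3). Of 26 targets of p53, 2 rose and 6 fell (median −0.19, 2 and 6 over the list alone, camera adjusted p = 0.00900, adjusted p = 0.271 with an estimated correlation). CDKN1A, the gene of the cell cycle inhibitor p21, went from 45.2 ± 1.12 to 29.5 ± 1.60 CPM (log2 −0.61, adjusted p = 0.00124, n = 3). Of 77 ribosomal protein genes 16 rose and 0 fell (median 0.15, 17 over the list alone, camera adjusted p = 3.01e-04, adjusted p = 0.910 with an estimated correlation). Scaled by library totals alone their median was −0.04, with 6 rising and 6 falling.

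In all, 2717 of the 14741 tested genes changed between mock and day 0, 1476 higher and 1241 lower, of which 561 by more than 2-fold. Without mock replicate 3, day 0 replicate 2 or day 0 replicate 3 the count is 1705, 1759 or 1730. Scaling by library totals alone lowers the median of all genes by −0.19 in this comparison and makes 18.9% of 4014 calls higher instead of 54.3%, so directions hold relative to the median gene. The nuclear genes of the respiratory chain turn as well, from a median of 0.10 to −0.09. Mock and day 0 are different transfected lines, so the fusion and the line cannot be told apart. Mock is titled as given doxycycline, without dose or duration, but on day 3, also with the drug, HBD (164 ± 14.1 CPM), FHOD3 (1177 ± 36.7), MT-CO1 (12300 ± 348), HSPA6 (0.663 ± 0.411) and BNIP3 (394 ± 51.0) were near day 0 and far from mock.

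On day 3, with AF4-MLL induced, many genes of respiration, ribosome assembly, cholesterol synthesis and the unfolded protein response fell. SQLE, the gene of squalene epoxidase in the making of cholesterol, went from 124 ± 2.95 to 65.6 ± 2.31 CPM, NCL, the nucleolin gene, from 611 ± 6.78 to 412 ± 12.1 CPM, and SDF2L1, a gene of the endoplasmic reticulum, from 388 ± 9.0 to 147 ± 3.85 CPM (n = 3). MYC, the gene of a transcription factor that drives ribosome synthesis, fell from 87.1 ± 6.58 to 56.7 ± 3.0 CPM. CDKN1A rose from 29.5 ± 1.60 to 57.9 ± 2.68 CPM, and HSPA1A, the gene of a stress-induced chaperone, from 0.765 ± 0.559 to 26.8 ± 3.80 CPM. CA2, the carbonic anhydrase 2 gene, fell from 316 ± 14 to 88.9 ± 8.59 CPM.

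The edgeR log2 changes were −0.91 for SQLE (SE 0.12, adjusted p = 4.72e-06), −0.57 for NCL (SE 0.10, adjusted p = 1.55e-04), −1.40 for SDF2L1 (SE 0.21, adjusted p = 2.75e-05), −0.62 for MYC (SE 0.11, adjusted p = 1.39e-04) and −1.83 for CA2 (SE 0.17, adjusted p = 5.08e-08). CDKN1A gained 0.97 (SE 0.13, adjusted p = 4.65e-06) and HSPA1A (chromosome 6, 31815464 to 31817946) 5.25 (SE 0.33, adjusted p = 6.29e-11). TNC, the gene of the matrix protein tenascin C, had 0 counts on day 0 and 6.10 ± 0.887 CPM on day 3, at least 30.2-fold higher against 3 counts over the group. PEG10, an imprinted gene of retrotransposon origin, reached 12.5 ± 2.53 CPM, a ratio of 92.5 (counting interval 25.1 to 771). HSPA1A, TNC and PEG10 are high on day 28 as well and low in the other groups, so they follow the pseudogene divide.

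The nuclear genes of the respiratory chain fell in 39 of 69 cases and 0 rose (median −0.35, 43 over the list alone, camera adjusted p = 8.76e-11, adjusted p = 0.616 with an estimated correlation). Ribosome biogenesis genes and MYC targets fell in 20 of 34 cases with 0 rising (median −0.44, 21 over the list alone, camera adjusted p = 1.74e-06, adjusted p = 0.616 with an estimated correlation). LYAR, the gene of a nucleolar growth regulator, went from 103 ± 9.63 to 57 ± 5.10 CPM (n = 3). Mitochondrial ribosome genes fell in 21 of 71 cases and 0 rose (median −0.28, 22 over the list alone, camera adjusted p = 4.16e-06, adjusted p = 0.751 with an estimated correlation). MRPL16, of the large subunit, was at −0.73. Of 23 cholesterol synthesis genes 14 fell and 9 did not pass (median −0.47, 15 over the list alone, camera adjusted p = 8.00e-06, adjusted p = 0.337 with an estimated correlation). SC5D, a sterol desaturase gene, was at −0.92. Unfolded protein response genes fell in 14 of 24 cases and 0 rose (median −0.59, 17 over the list alone, camera adjusted p = 9.91e-05, adjusted p = 0.659 with an estimated correlation). Proteasome genes fell in 12 of 30 cases and 0 rose (median −0.30, 15 over the list alone, camera adjusted p = 2.08e-04, adjusted p = 0.811 with an estimated correlation). PSMA3, of the core particle, was at −0.84. Heat shock genes did not pass as a list, with 3 of 20 rising and 3 falling (camera adjusted p = 0.687). Of 10 histone genes 6 rose, 1 fell and 3 did not pass (median 1.06, 6 and 1 over the list alone, camera adjusted p = 0.00284, adjusted p = 0.327 with an estimated correlation). H1F0, the gene of the linker histone of resting cells, rose from 56.8 ± 10.2 to 191 ± 0.432 CPM (n = 3) and was chosen after its values were seen.

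In all, 4180 genes changed on day 3 against day 0, 1961 higher and 2219 lower, 1191 of them by more than 2-fold. The balance depends on scaling: library totals alone make 53.9% of 4055 calls higher instead of 46.9%. Coding genes with unique ends had 779 calls higher and 1588 lower in the main fit. Fitted and scaled by themselves they had 1057 higher and 1059 lower. Day 3 lies across the pseudogene divide from day 0 and no label gives a batch, so in genes that follow the divide induction and a library batch cannot be told apart, and in this comparison induction and doxycycline go together. Against day 28, on the same side of the divide, day 3 differed in the same direction in 2129 of the 4180 genes, 848 higher and 1281 lower. These hold 61.2% of the 2367 changed coding genes with unique ends and 16.4% of the 791 changed pseudogenes. The day 3 libraries enter both of these comparisons. In simulated data without any change this sharing gave a correlation of 0.574, against 0.566 observed. A correlation does not depend on the size of the changes, so these values cannot show how many of the genes differ. The simulated overlap was 0 genes in 10 draws, but without change almost no gene is called. That overlap therefore cannot show how many of the 2129 genes owe their place to the shared libraries.

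On day 12 the genes of protein folding in the endoplasmic reticulum and of the amino acid response fell. HSPA5 (chromosome 9, 125234853 to 125241330), the gene of the reticulum chaperone BiP, went from 1025 ± 13.9 to 214 ± 4.61 CPM, and MANF, the gene of a secreted survival factor of that stress response, from 566 ± 14.3 to 126 ± 1.78 CPM (n = 3). ATF4, the transcription factor gene of the amino acid response, fell from 1092 ± 36.5 to 657 ± 48.5 CPM and SLC3A2, an amino acid transporter gene, from 360 ± 6.58 to 147 ± 9.43 CPM. CDKN1A fell to 16.4 ± 2.85 CPM, while SRSF11, a splicing factor gene, rose from 107 ± 4.13 to 168 ± 10.9 CPM. HOXA9 (chromosome 7, 27162435 to 27175180), a homeobox gene and known target of MLL fusions in leukaemia, rose from 61.6 ± 4.54 to 88.6 ± 0.714 CPM.

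The edgeR log2 changes were −2.26 for HSPA5 (SE 0.26, adjusted p = 8.95e-05), −2.16 for MANF (SE 0.26, adjusted p = 8.95e-05), −0.73 for ATF4 (SE 0.14, adjusted p = 0.00329), −1.29 for SLC3A2 (SE 0.20, adjusted p = 7.58e-04), −0.85 for CDKN1A (SE 0.14, adjusted p = 0.00118) and 0.64 for SRSF11 (SE 0.09, adjusted p = 3.82e-04). HOXA9 gained 0.52 (SE 0.13, adjusted p = 0.0180), a call that is lost when day 0 replicate 2 or 3 or day 12 replicate 2 or 3 is left out (adjusted p = 0.0577 to 0.0726). Other genes cover 31.3% of the 3' end sequence of HOXA9 and 58.1% of that of ATF4. DNAJB9, a reticulum co-chaperone gene, fell from 56.5 ± 5.16 to 11.7 ± 1.01 CPM (−2.27, SE 0.30, adjusted p = 2.26e-04, n = 3) and NUPR1, a stress-induced chromatin factor gene, from 10.4 ± 1.45 to 1.59 ± 0.534 CPM (−2.69, SE 0.55, adjusted p = 0.00536).

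Of 24 unfolded protein response genes, 21 fell and 0 rose (median −1.21, 21 over the list alone, camera adjusted p = 3.43e-23, adjusted p = 0.145 with an estimated correlation). The ATF4 response fell in 31 of 35 genes and rose in 0 (median −1.02, 33 fell over the list alone, camera adjusted p = 3.01e-23, adjusted p = 0.305 with an estimated correlation). Ribosomal protein genes fell in 33 of 77 cases and 0 rose (median −0.31, 66 fell and 1 rose over the list alone, camera adjusted p = 2.30e-16, adjusted p = 0.583 with an estimated correlation). Hosts of small nucleolar RNAs fell in 10 of 12 cases and 1 rose (median −0.60, 11 and 1 over the list alone, camera adjusted p = 1.29e-06, adjusted p = 0.487 with an estimated correlation). Splicing factor genes rose in 12 of 37 cases and fell in 2 (median 0.30, 19 and 2 over the list alone, camera adjusted p = 2.75e-07, adjusted p = 0.487 with an estimated correlation). SNRNP70, of the U1 particle, was at 0.75. Proteasome genes rose in 7 of 30 cases with 0 falling (median 0.30, 13 over the list alone, camera adjusted p = 6.90e-08, adjusted p = 0.591 with an estimated correlation). Heat shock genes rose in 8 of 20 cases with 0 falling (median 0.49, 11 rose and 1 fell over the list alone, camera adjusted p = 1.30e-06, adjusted p = 0.531 with an estimated correlation). HSP90AA1, the gene of inducible HSP90, went from 789 ± 48.4 to 1504 ± 193 CPM (n = 3) and was also chosen after its values were seen. Hypoxia genes fell in 9 of 20 cases (median −0.50, 12 over the list alone, camera adjusted p = 1.82e-06, adjusted p = 0.531 with an estimated correlation).

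In all, 1822 genes changed on day 12 against day 0, 700 higher and 1122 lower, 257 by more than 2-fold. Leaving out any library of either group lowers this to between 432 (without day 12 replicate 3) and 1253, with 498 without day 12 replicate 2, and 850, 554 and 506 without day 0 replicates 1, 2 and 3. Library totals alone turn the balance, with 69.7% of 2289 calls higher instead of 38.4%.

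**Figure D3:**
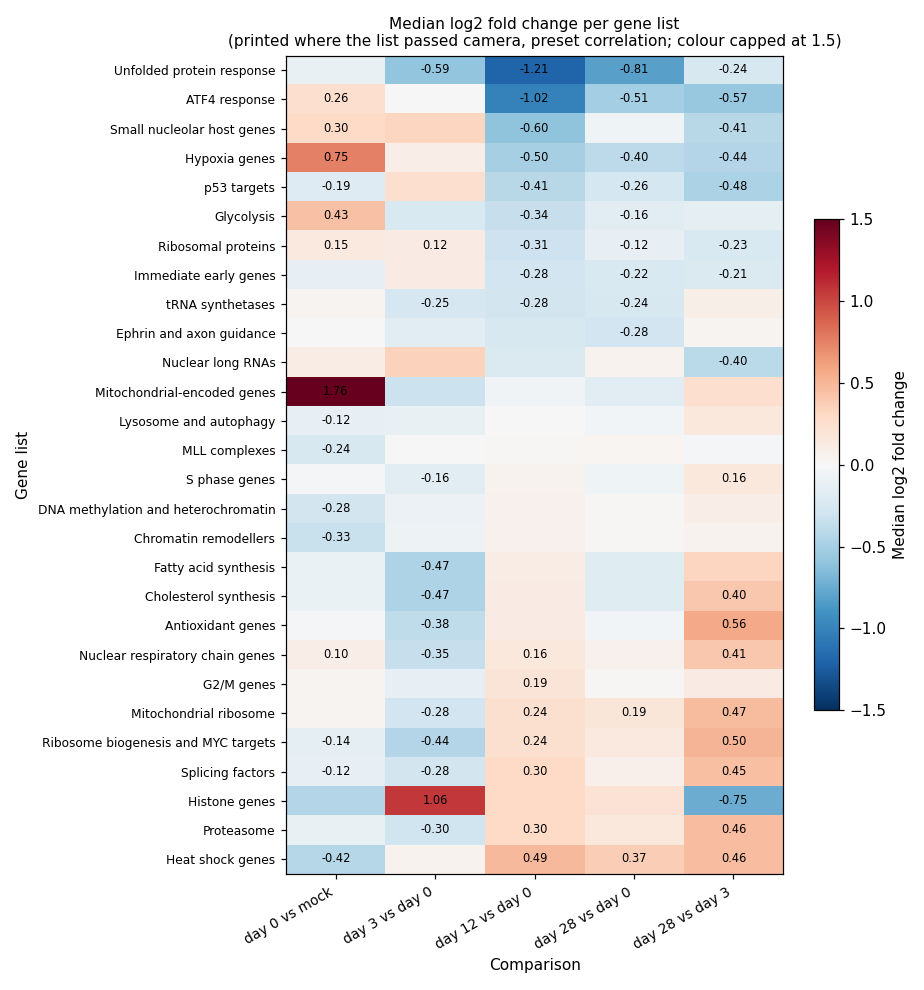
Median log2 fold change of each gene list (vertical) in 5 comparisons (horizontal), coloured from blue (lower) to red (higher), with the value written where the list passed camera at a preset correlation. The unfolded protein response is at −0.59 on day 3, −1.21 on day 12 and −0.81 on day 28 against day 0; ribosomal proteins, at 0.15 on day 0 against mock, turn to −0.04 when scaled by library totals alone.

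By day 28 many reticulum genes and some amino acid genes were still below day 0, but the mean of the ATF4 response in replicate 1 was near day 0 (−0.06). Some genes that were near absent on day 0 and higher on day 3 were high again. HSPA5 stood at 420 ± 289 CPM, with 754 in replicate 1, 236 in replicate 2 and 271 in replicate 3, against 1025 ± 13.9 on day 0 (n = 3). PSAT1, a gene of serine synthesis, fell from 367 ± 13.9 to 213 ± 36.1 CPM and PMAIP1, the gene of the p53 target NOXA, from 119 ± 6.31 to 75.9 ± 11.7 CPM. HSPA1A was at 21.6 ± 3.38 CPM against 0.765 ± 0.559 on day 0 and 4.85 ± 0.754 in mock, and TNC at 5.55 ± 1.35 CPM against 0 on day 0 and 0.718 ± 0.330 in mock. CDKN1A was at 16.5 ± 3.06 CPM, and HOXA10, a homeobox gene beside HOXA9, fell from 108 ± 6.81 to 77.0 ± 2.70 CPM.

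The edgeR log2 changes were −1.28 for HSPA5 (SE 0.25, adjusted p = 8.98e-04), −0.79 for PSAT1 (SE 0.11, adjusted p = 1.38e-05), −0.64 for PMAIP1 (SE 0.11, adjusted p = 2.59e-04), −0.83 for CDKN1A (SE 0.14, adjusted p = 1.40e-04), −0.49 for HOXA10 (SE 0.09, adjusted p = 5.45e-04) and 4.94 for HSPA1A (SE 0.33, adjusted p = 2.46e-10). The call of HSPA5 is lost when only these groups are fitted. TNC was at least 28.9-fold higher. NOV, the gene of a matricellular growth regulator, was at 12 ± 2.05 CPM (n = 3), a ratio of 59.7 (counting interval 20.2 to 292).

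Unfolded protein response genes fell in 19 of 24 cases and 0 rose (median −0.81, 22 over the list alone, camera adjusted p = 8.49e-16, adjusted p = 0.370 with an estimated correlation), and ATF4 response genes in 15 of 35 with 0 rising (median −0.51, 21 over the list alone, camera adjusted p = 4.18e-11, adjusted p = 0.642 with an estimated correlation). Targets of p53 fell in 7 of 26 cases with 0 rising (median −0.26, 9 fell and 1 rose over the list alone, camera adjusted p = 0.00129, adjusted p = 0.370 with an estimated correlation). Heat shock genes rose in 8 of 20 cases with 0 falling (median 0.37, 11 over the list alone, camera adjusted p = 0.00177, adjusted p = 0.642 with an estimated correlation). Relative to day 0, the mean of the unfolded protein response list was −0.28 in day 28 replicate 1, −1.28 in replicate 2 and −1.19 in replicate 3, that of the ATF4 response −0.06, −0.57 and −1.30, and that of heat shock genes 0.11, 0.40 and 0.99. In all, 2022 genes changed, 1169 higher and 853 lower, 742 by more than 2-fold. Of the 2022, 845 are pseudogenes (734 higher, 111 lower) and 774 coding genes with unique ends (242 higher, 532 lower). Without day 28 replicate 1 the count is 4042, and library totals alone make 68.6% of 1998 calls higher instead of 57.8%. With only these groups in the fit the count is 908. The shared noise estimate is thus likely too small for day 28, and the gene p-values and member counts given here too favourable. Day 28 also lies across the pseudogene divide from day 0, so time and a library batch cannot be told apart here.

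HOX genes and a list of MLL-AF4 targets from leukaemia did not pass camera against day 0. At the preset correlation alone, the HOXA list passed as higher on day 12 than in mock. Both HOX lists passed in the same way as lower on day 28 than on day 12, with few members called. HOXA10 rose from 84.2 ± 2.85 CPM in mock to 108 ± 6.81 on day 0 (log2 0.36, SE 0.09, adjusted p = 0.00748, n = 3), fell to 64.7 ± 4.36 on day 3 (−0.74, SE 0.09, adjusted p = 3.76e-06) and did not differ from day 0 on day 12 (111 ± 2.77 CPM, adjusted p = 0.824). The first of these HOXA10 calls is lost without day 0 replicate 1 (0.30, adjusted p = 0.0547) and with library totals alone. Of 15 HOXA cluster genes, 4 rose on day 0 against mock (camera adjusted p = 0.132), 3 rose and 5 fell on day 3 (median −0.28 but mean 0.07; adjusted p = 0.524), 1 rose on day 12 (adjusted p = 0.0710) and 1 fell on day 28 (adjusted p = 0.776), each against day 0. In the added comparison of day 12 with mock, 7 of the 15 rose and 0 fell (median 0.60, camera adjusted p = 0.00263, adjusted p = 0.306 with an estimated correlation). On day 28 against day 12, 1 HOXA gene fell and 0 rose (median −0.30, camera adjusted p = 0.0332), and 3 of 9 HOXB genes fell and 0 rose (median −0.44, camera adjusted p = 0.0106), each with adjusted p = 0.766 with an estimated correlation. The HOXA mean of day 28 replicate 2 equals the lowest of day 12 (0.14). HOXB means relative to day 0 were 0.29, −0.01 and 0 on day 12 and −0.42, 0.01 and −0.45 on day 28. Day 28 replicate 2 thus lay above day 12 replicates 2 and 3 in HOXB genes. HOXB genes did not pass on day 0 against mock, where 1 rose and 2 fell (median 0.30 but mean −0.06, adjusted p = 0.844), nor against day 0 on day 3 (1 fell, adjusted p = 0.718), day 12 (1 rose, adjusted p = 0.511) or day 28 (1 fell, adjusted p = 0.0946). Of 33 MLL-AF4 targets 3 rose and 2 fell on day 0 (adjusted p = 0.928), 3 rose and 7 fell on day 3 (median −0.20, adjusted p = 0.136, but 4.69e-04 in fry, a test that does not compare the list with other genes), 1 rose and 1 fell on day 12 (adjusted p = 0.660) and 1 rose and 3 fell on day 28 (adjusted p = 0.381). MEIS1, a HOX cofactor gene, did not pass in any comparison with day 0, but was lower than in mock on day 28 (−0.50, adjusted p = 0.0120, an added comparison) and on day 3 (8.18 ± 1.66 against 13.1 ± 0.462 CPM, log2 −0.67, SE 0.16, adjusted p = 0.00238, n = 3).

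Between mock and day 3, hypoxia genes were higher and ribosome biogenesis genes lower, while CDKN1A, which fell from mock to day 0 (−0.61) and rose to day 3 (0.97), and HOXA10 (0.36, then −0.74) moved in opposite directions in the steps between. MROH8, a gene of unknown function, stood at 95.2 ± 9.22 CPM on day 3 against 1.55 ± 0.763 in mock (log2 5.83, SE 0.22, adjusted p = 2.38e-15, n = 3). SPARC, a matrix protein gene, fell from 19.1 ± 1.29 to 3.90 ± 1.61 CPM (−2.26, SE 0.23, adjusted p = 5.05e-08). The hypoxia genes were higher in 15 of 20 cases (median 0.73, camera adjusted p = 4.90e-05, adjusted p = 0.465 with an estimated correlation), and ribosome biogenesis genes and MYC targets lower in 26 of 34 (median −0.53, camera adjusted p = 3.46e-08, adjusted p = 0.428 with an estimated correlation). In all, 6531 genes differed, 3180 higher and 3351 lower. The comparison crosses the pseudogene divide: 988 of the higher and 139 of the lower genes are pseudogenes. Coding genes with unique ends had 1288 calls higher and 2544 lower. With library totals alone 33.3% of 7438 calls were higher instead of 48.7%, the median of all genes moving by −0.15; scaling within coding genes with unique ends moves it by 0.12.

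Between day 3 and day 12 many genes of respiration, ribosome assembly and the proteasome rose, and the unfolded protein response fell further. CA2 went from 88.9 ± 8.59 to 550 ± 29.4 CPM (log2 2.63, SE 0.18, adjusted p = 1.27e-10, n = 3) and LYAR from 57 ± 5.10 to 132 ± 18 CPM (1.21, SE 0.14, adjusted p = 7.87e-07). PPP1R15A, the gene of a phosphatase subunit that ends the integrated stress response, fell from 118 ± 3.73 to 19.6 ± 5.30 CPM (−2.60, SE 0.25, adjusted p = 4.12e-08). Nuclear respiratory chain genes rose in 53 of 69 cases and 0 fell (median 0.50, camera adjusted p = 5.48e-13, adjusted p = 0.483 with an estimated correlation), and mitochondrial ribosome genes in 56 of 71 with 1 falling (median 0.50, camera adjusted p = 7.09e-11, adjusted p = 0.483 with an estimated correlation). Ribosome biogenesis genes and MYC targets rose in 27 of 34 cases (median 0.71, camera adjusted p = 6.63e-10, adjusted p = 0.483 with an estimated correlation), and proteasome genes in 23 of 30 (median 0.61, camera adjusted p = 5.33e-09, adjusted p = 0.483 with an estimated correlation), with 0 falling in either. The unfolded protein response fell in 16 of 24 genes and rose in 2 (median −0.76, camera adjusted p = 3.73e-04, adjusted p = 0.524 with an estimated correlation). The ATF4 response fell in 30 of 35 genes and rose in 1 (median −1.12, camera adjusted p = 5.33e-09, adjusted p = 0.483 with an estimated correlation). In all, 6862 genes changed, 3458 higher and 3404 lower. The comparison crosses the pseudogene divide.

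Between day 12 and day 28 the fewest coding genes with unique ends were called of any comparison in the main fit, 597 of 9794. All groups share the noise estimate of this fit, so the spread of the day 28 libraries does not single out this comparison. With only these groups in the fit, 848 genes of all kinds changed instead of 1755. The SD of log2 changes over coding genes with unique ends was 0.364, against 0.688 for day 12 with day 3 and 0.355 for day 28 with day 0. The day 28 libraries differ widely from each other, so few calls do not show that little changed. HMMR, a gene of the mitotic spindle, fell from 44.1 ± 3.62 to 28 ± 3.01 CPM (log2 −0.66, SE 0.14, adjusted p = 0.00164, n = 3), and KIFC1, a mitotic motor gene, from 39.8 ± 5.83 to 19.6 ± 1.64 CPM (−1.02, SE 0.12, adjusted p = 1.63e-06). G2/M genes fell in 5 of 54 cases and 0 rose (median −0.16, camera adjusted p = 2.28e-04, adjusted p = 0.766 with an estimated correlation). ATF4 response genes rose in 7 of 35 cases (median 0.42, camera adjusted p = 0.00231, adjusted p = 0.766 with an estimated correlation). Relative to day 0 the list mean was −0.06, −0.57 and −1.30 in day 28 replicates 1, 2 and 3 and −0.85, −1.12 and −1.04 on day 12, so replicate 3 lay below every day 12 library. TRIB3, a pseudokinase gene of that response, was at 1.48 (adjusted p = 0.00965) with overlapping libraries, at 0.50 (adjusted p = 0.181) without day 28 replicate 1 and at 1.41 (adjusted p = 0.0502) without day 12 replicate 2. In all, 1755 genes changed, 1201 higher and 554 lower, of which 851 are pseudogenes and 597 coding genes with unique ends. Leaving out day 28 replicate 3 raises the count to 4096, leaving out day 12 replicate 3 lowers it to 1128, and without day 28 replicate 1 the number of changed lists drops from 13 to 1. The percentage higher is 68.4% and becomes 57.3% of 1901 with library totals alone.

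Over the fusion groups as a time course, 7255 of 14741 genes (49.2%) changed by the joint test. Of the genes changed on day 3, 1201 were changed in the same direction on day 28, 766 higher and 435 lower, and 18 in the opposite direction; 284 would be expected from independent lists. Both comparisons use the day 0 libraries, which alone gave a correlation of 0.492 between log2 changes in simulated data without any change, against 0.688 observed, and a mean overlap of 0.1 genes. Without change almost no gene is called, so this overlap cannot show how many of the 1201 genes come from the shared libraries. The 3 control libraries cannot be split into parts of 2 libraries each. Of the 1201, 651 are pseudogenes and 321 coding genes with unique ends, out of 2367 of the latter changed on day 3. Over all coding genes with unique ends the correlation was 0.394 against 0.491 simulated. Day 28 shared more of these genes with day 12: 343 of the 1216 changed on day 12 were changed in the same direction. Their correlation was 0.555 against 0.513 simulated, again over all coding genes with unique ends. A correlation does not depend on the size of the changes, so these values alone cannot show what is shared beyond the libraries. For day 3 and day 28 the covariance, which depends on the size of the changes, exceeded the simulated value by 0.249 over all genes and by 0.0449 over the coding genes with unique ends. For day 12 and day 28 the excess was 0.0451 and 0.0546. No list call in this report holds with an estimated correlation between genes.

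**Figure D4:**
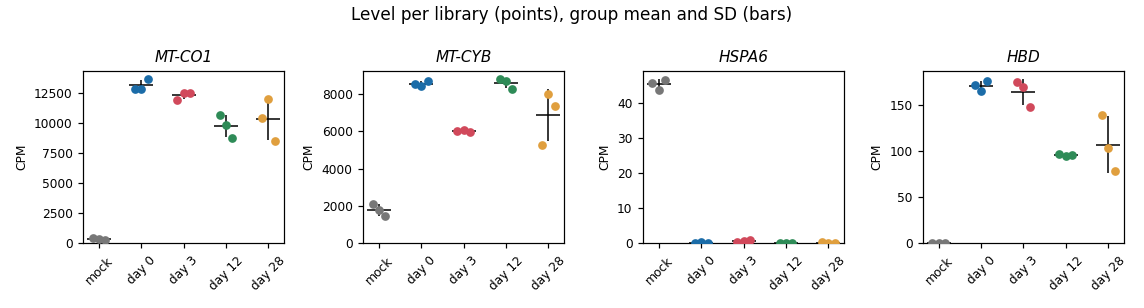
CPM of MT-CO1, MT-CYB, HSPA6 and HBD by group, 1 point per library, with bars for the group mean ± SD (n = 3). Mock alone is high in HSPA6 (45.3 CPM), lacks HBD (0 CPM) and is low in MT-CO1 (343 CPM) and MT-CYB (1793 CPM).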

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

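The tests of the pseudogene, mitochondrial and HBD patterns, and those by other divisions of the libraries, were written down only after the results were seen. Of 107 named genes checked for opposite changes on day 3 and on a later day, both against day 0, 13 were found. The named genes were selected in part for large changes between these days, so their share does not stand for all genes. Over all tested genes, 398 changed in opposite directions on day 3 and day 12, and 18 on day 3 and day 28. The difference between the days is given from edgeR, but opposite and passing changes all but fix that it passes, so its adjusted p describes its precision and is no separate evidence.

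Cell cycle and stress genes are among them. CDKN1A rose on day 3 (0.97) and was below day 0 on day 12 (−0.85) and day 28 (−0.83), with direct differences of −1.82 (SE 0.13, adjusted p = 5.82e-10) and −1.79 (SE 0.13, adjusted p = 1.55e-08). NUPR1 went from 1.77 to −2.69 (difference −4.47, adjusted p = 1.12e-07). PPP1R15A went from 1.53 to −1.07 (−2.60, adjusted p = 4.12e-08). AKNA, a centrosome gene, went from 1.06 to −2.51 (−3.58, adjusted p = 6.28e-06), and MAP6, a microtubule gene, from 2.03 to −1.74 (−3.77, adjusted p = 1.80e-07).

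Genes that were low on day 3 and high on day 12 include CA2, with a difference of 2.63 (adjusted p = 1.27e-10), and HMGN5, a nucleosome-binding gene, with 2.58 (adjusted p = 1.33e-08), although HMGN5 libraries of day 12 overlap those of day 0. GAP43, a growth cone gene, had 3.04 (adjusted p = 9.17e-07), PLA2G4A, a phospholipase gene, 2.37 (adjusted p = 7.31e-06), and CAMKMT, a methyltransferase gene, 1.85 (adjusted p = 7.26e-06). WDR12, of ribosome assembly, rose from −0.43 to 0.58 on day 12 (difference 1.01, adjusted p = 4.76e-06) and to 0.43 on day 28 (difference 0.86, adjusted p = 2.38e-04). PSMD1, of the proteasome, had 1.54 (adjusted p = 1.18e-05), but its day 12 change from day 0 does not pass without day 0 replicate 3 or day 12 replicate 3 (adjusted p = 0.0590 and 0.0578). In the other direction, RPL28, of the ribosome, went from 0.30 to −0.43 (difference −0.73, adjusted p = 1.05e-05), and its day 12 change does not pass without replicate 2 or 3 of day 0 or of day 12 (adjusted p = 0.0583 to 0.0773). Both differences between day 3 and day 28 lie on 1 side of the pseudogene divide, while those between day 3 and day 12 cross it.

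The numbers of changed genes and lists were compared with other divisions of the same libraries. For each comparison of 3 with 3 libraries there are only 10 divisions, too few for a share under 0.05. For genes, the real division alone (1 of 10) gave its count, and the highest of the others was 0 except for day 28 with day 12, where it was 731 against 1755. For lists the real counts and the highest others were 15 and 11 for day 0 with mock, 13 and 11 for day 3 with day 0, 16 and 15 for day 12 with day 0, 20 and 16 for day 3 with mock, and 18 and 15 for day 28 with day 3. For day 28 with day 0 they were 11 and 19, with 9 of the 10 divisions giving as many. For day 12 with day 3 they were 16 and 17 (3 of the 10), and for day 28 with day 12 they were 13 and 16 (7 of the 10), so list counts alone say little there. In the joint test only the real division among 100 gave as many as 7255 genes, the highest other giving 2227. Mixed divisions carry group differences into the estimate of noise, which lowers their counts. As the libraries of a group may also be technical, this cannot exclude chance differences between cultures. For the genes shared by day 3 and day 28, 3 of 100 divisions gave as many as 1201. The highest, 1451, had the day 3 libraries as the reference.

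Day 3 and day 28 share pseudogene counts that the other groups lack: of 176 genes more than 4-fold higher on both days than on the other days and in mock, 154 are processed pseudogenes and 8 are coding genes with unique ends. A division of reads between parents and their copies that differs between libraries is a candidate explanation. Over 351 families the Spearman correlation between the changes of a parent and of its pseudogenes was −0.00258 for day 28 with day 12, against 0.762 for day 12 with day 0 and 0.761 for day 28 with day 3. The other comparisons do not split as cleanly. Across the divide it was −0.0665 for day 3 and −0.149 for day 28 with day 0, and 0.103 and −0.0702 with mock. Day 12 with day 3 also crosses the divide and gave 0.361. On the same side, day 0 and day 12 with mock gave 0.472 and 0.342. Transgene RNA present at the time is an unlikely source. The median log2 pseudogene change from day 0 was 0.555 on day 3 and 0.687 on day 28, or 124%. KMT2A kept 3.2% of its rise, on the different scale of CPM (33.0 on day 0, 313 on day 3 and 41.9 on day 28). A lasting effect of earlier induction, which the labels leave open, is not excluded by this. A library batch stays open: the SD of pseudogene log2 changes was 0.482 between day 28 and day 3 and 1.24 between day 28 and day 12, but no label gives a batch and the coding genes with unique ends that share the pattern, CD44, TNC, PLP2, NOV, COL6A3, SLFN11, HSPA1A and PEG10, do not tell a batch from biology.

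Mock had few mitochondrial counts. Counting of these reads at nuclear copies is an unlikely cause, since the copies also stood at 13.2% of their day 0 level. Doxycycline for 48 h as on day 3 is unlikely to suffice, since day 3 kept 84.9% of the mitochondrial share of day 0, but the labels give no dose or duration for mock, so a longer or stronger treatment is not excluded. A lower yield of all mitochondrial RNA alike leaves MT-CO1 unexplained, as its log2 change exceeded the next largest by 2.99 among 11 abundant protein-coding mitochondrial genes, and the transfer RNA MT-TV moved the other way. A biological difference between the lines was not tested and remains open.

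HBD was counted in all 12 fusion libraries and had 0 of 23360341 counts in mock. Activation of the beta-globin cluster stays open, since HBB counts were only 1.99% of those of HBD but HBB too was at 0 in mock and at 0.992 to 4.55 CPM of all counts in the fusion libraries. Sequence of the constructs, or a place of insertion that the mock line lacks, could give such counts, and the lowest HBD level in a fusion library was 75.9 CPM of all counts. Without reads this remains open. FHOD3 may belong with it, but on day 12 it was at 35.7% of its day 0 level and HBD at 56.0%.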

How the results depend on the processing

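The fits within coding genes with unique ends, without mitochondrial genes and without the day 28 group were chosen only after the results were seen; the other alternatives were planned. In the alternatives run for named genes, which leave out these fits, no called direction was reversed: of 4161 alternative values 210 lost the call and 20 gained it. Tests against a fold of 1.5 account for 84 of the losses and leaving out a library for 90.

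Counts of changed genes depend on the minimum fold, on the genes tested and on whether day 28 is in the fit. Tested against a fold of 1.5, 261 genes changed between mock and day 0, and against day 0 781 on day 3, 25 on day 12 and 530 on day 28. The same test gave 1856 for day 3 with mock, 1944 for day 12 with day 3 and 591 for day 28 with day 12. With only the groups compared in the fit, day 0 with mock gave 4919 and day 12 with day 0 4051, while day 28 gave 908 with day 0 and 848 with day 12. Without the day 28 group, day 0 with mock gave 4755 and day 12 with day 0 4252. Including the spread-out day 28 libraries in the shared estimate of noise thus lowers the counts of the other comparisons. The same sharing raises the counts of day 28 with day 0 and with day 12, as the shared estimate is likely too small for the day 28 libraries. Main p-values and calls of genes on day 28 are therefore likely too favourable.

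Within coding genes with unique ends the counts were 1610 for day 0 with mock, 2116, 406 and 3421 for day 3 with day 0, day 28 with day 0 and day 3 with mock, 4281 for day 12 with day 3, 246 for day 28 with day 12 and 4287 for the joint test. The genes shared by day 3 and day 28 fell from 1201 to 181 there, to 394 against a fold of 1.5, and to 247 with day 12 in place of day 28. For day 3 and day 12, 262 would be expected from independent lists, and 398 genes changed in opposite directions. With mock as the reference of both, the genes shared by day 3 and day 28 were 3174. With mock as the reference of day 28 alone, so that no library is shared, they were 1552.

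Leaving out 1 library gave 1705 (without mock replicate 3) to 1874 genes for day 0 with mock, 1759 without day 0 replicate 2 and 1730 without day 0 replicate 3. For day 12 with day 0 it gave 432 (without day 12 replicate 3) to 1253, for day 28 with day 0 1373 to 4042 (without day 28 replicate 1), and for day 28 with day 12 1128 (without day 12 replicate 3) to 4096 (without day 28 replicate 3). Lists for day 28 with day 0 ranged from 4 (without day 28 replicate 3) to 15, and for day 28 with day 12 from 1 (without day 28 replicate 1) to 14. With an estimated correlation 0 lists changed in any comparison. By fry 22 changed on day 3 and 6 on day 28 against day 0, 31 for day 12 with day 3 and 6 for day 28 with day 12. Within coding genes with unique ends, 11 changed for day 3 with mock.

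With the replicate number as a replicate block the counts were 2662 for day 0 with mock and 4184, 1792 and 1979 for day 3, day 12 and day 28 with day 0. The numbers do not appear to pair libraries, since correlations of libraries with the same number ran from −0.0738 to 0.165 and 6 of 15 libraries were closest to their own number. DESeq2 gave 2207, 3564, 1760 and 1711 in the same order.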

Other observations

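The comparisons of day 28 with day 3, the lists by library and the genes picked here were chosen only after the results were seen. Several lists that were lower on day 3 than on day 0 were higher on day 28 than on day 3. Nuclear respiratory chain genes were higher on day 28 than on day 3 in 48 of 69 cases and lower in 0 (median 0.41, camera adjusted p = 5.33e-16, adjusted p = 0.406 with an estimated correlation). Ribosome biogenesis genes and MYC targets were higher in 26 of 34 cases (median 0.50, camera adjusted p = 1.73e-12, adjusted p = 0.406 with an estimated correlation), and mitochondrial ribosome genes in 52 of 71 with 1 lower (median 0.47, adjusted p = 0.427 with an estimated correlation). Targets of p53 were lower in 13 of 26 cases (median −0.48, camera adjusted p = 5.78e-07, adjusted p = 0.0872 with an estimated correlation). In all, 3862 genes differed, 2212 higher and 1650 lower, and only 332 of them are pseudogenes.

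Some stress genes were higher on day 3 than on day 12. GDF15, a secreted stress cytokine gene, stood at 6.96 ± 3.20 CPM in mock, 1.18 ± 0.506 on day 0, 8.54 ± 1.76 on day 3 and 0.427 ± 0.256 on day 12 (n = 3, log2 −4.28, SE 0.59, edgeR adjusted p = 5.15e-06), and INHBE, an activin subunit gene of the integrated stress response, at 6.78 ± 0.928 on day 3, 2.06 ± 0.278 in mock and 0.156 ± 0.270 on day 12. The ATF4 response as a list did not pass on day 3 against day 0, with 4 of 35 genes rising and 4 falling (camera adjusted p = 0.908). FKBP10, a collagen-folding gene, fell from 203.6 ± 9.72 CPM in mock, against 48.4 ± 16 on day 0, to 36.3 ± 3.59 on day 3 (−2.49, SE 0.30, adjusted p = 7.74e-07, n = 3).

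The libraries of day 28 differ from each other in the same stress genes. ATF4 stood at 1024 CPM in replicate 1, 715 in replicate 2 and 555 in replicate 3, and DDIT3, the gene of the pro-apoptotic factor CHOP, at 99.4, 23.1 and 9.22. FHOD3 stood at 1164, 654 and 335 and HBD at 139, 103 and 78.0. The mean of heat shock genes relative to day 0 was 0.11, 0.40 and 0.99. Over coding genes with unique ends replicate 3 lay at −17.6 on component 1, beside day 12, while over all genes the 3 libraries lay on the side of day 3.

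EGR1, an immediate early gene fixed beforehand, did not pass between mock and day 0 (1.28 ± 0.272 to 2.89 ± 0.619 CPM, log2 1.16, adjusted p = 0.0517, n = 3). It was higher on day 3 than in mock (1.48, adjusted p = 0.00585), a call lost without day 3 replicate 3 (adjusted p = 0.0787). It was higher on day 12 (7.05 ± 2.96 CPM, n = 3) than on day 0 (2.89 ± 0.619 CPM, adjusted p = 0.0176), a call lost without day 0 replicate 1 or 2 or day 12 replicate 1 or 3 (adjusted p = 0.0507 to 0.0792). The rise from day 3 to day 12 (0.98, adjusted p = 0.0203) is lost without day 3 replicate 1 or 2 or day 12 replicate 1 (0.63 without the last, adjusted p = 0.144). The fall from day 12 to day 28 (−1.12, adjusted p = 0.0191) is lost without day 12 replicate 1 or day 28 replicate 1 or 2 (adjusted p = 0.0597 to 0.145), and in both of these steps libraries of the groups overlap. In the added comparisons with mock, EGR1 was higher on day 12 (2.46, adjusted p = 3.05e-05) and day 28 (1.34, adjusted p = 0.00991).

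In RPL39 the pseudogenes went from 1840 CPM on day 0 to 4300 on day 3 while the parent went from 3540 to 2540. In RPL38 the pseudogenes went from 573 to 220 and the parent from 3340 to 4900. In RPS18 both rose, the pseudogenes from 92.7 to 585 and the parent from 1730 to 2510. Over 351 families the Spearman correlation between parent and pseudogene changes was −0.0665 for day 3 with day 0, so opposite changes are no general rule.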
